A study of Homo sapiens with 12 samples.

How the data were processed

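RNA was sequenced from 12 samples of the CHLA-01-MED line, 3 in each of 4 groups. Per the labels' protocols, 1 ug of total RNA went into the TruSeq Stranded Total RNA kit, and cells grew in DMEM/F-12 with B-27, EGF and bFGF at 20 ng/ml each. The groups and replicate numbers were taken from the sample titles. Nothing in the labels names a batch, a date or separate cultures.

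The authors deposited a table of raw counts per gene, with 1 column per sample and no pooling. The authors also deposited a table of TPM values, which are counts divided by gene length and scaled to a fixed sum per sample. The submitters' processing notes name bcl2fastq 2.20, STAR 2.4.2a, featureCounts 2.0.1, DESeq2 1.34.0 and the build GRCh38.p13, without their role or order. The annotation, the strand setting and any filter are not given in the sources used here. Both deposited tables hold 1 entry per gene. Each TPM value was checked to be the count rescaled by 1 factor per gene and 1 per sample, with a largest relative departure of 2.49e-15 over 14034 genes. A test of SMYD3 transcripts had been planned for the case of 1 entry per transcript, and it was not run. The gene-level limma fit on log2(TPM + 1) was run instead, as an alternative to the count test.

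The count table has 90517 genes, of which 31037 carry clone-style names and 37723 have a position in GENCODE 29, the annotation of GRCh38 used for coordinates. Entries were matched to GENCODE by symbol, where a symbol names 1 gene. RIGI is listed as DDX58, and SPRIGHTLY has no entry under its symbol and was not analysed here. Total counts per library ran from 15752736 to 21130937. A floor of 3 counts covers counting error only. Pairs of replicates were compared by a chi-square statistic over at least 15527 genes with 40 or more counts in the pair. It came to between 1.92 and 3.84 per degree of freedom, so no pair was counted as 1 library.

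Differences were tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. The quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) used all 12 libraries in 1 fit, with TMM factors and the filterByExpr filter, which left 23374 genes. Tests were two-sided, and p-values were adjusted by Benjamini-Hochberg within a comparison, with calls at 0.05. Standard errors are the absolute log2 fold change divided by the square root of F. The 4 main comparisons were IT1_del, SMYD3_Myc and SMYD3_E5Del_Myc against vo, and SMYD3_E5Del_Myc against SMYD3_Myc. IT1_del was also contrasted with SMYD3_E5Del_Myc, as the test of a difference between their effects. Gene lists (32 of them) were tested with camera of limma 3.58.1, at a preset correlation of 0.01 and with an estimated one, and with fry. List p-values were adjusted over the lists within a comparison. Members were also counted after being adjusted over the list alone.

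Named genes followed a rule with 4 parts. The first is SPRY4-IT1, SPRY4, SMYD3 and PTBP1. Next come the 6 largest rises and 6 largest falls by log2 fold change among called genes with a mean CPM of at least 5 over the 6 libraries and all 3 libraries of one group above all 3 of the other. Unnamed and clone-style entries, pseudogenes, mitochondrial genes, XIST and Y-linked genes were left out of that part. For the 5 lists with the smallest preset-correlation camera p, up to 4 called members with the smallest p were named, leaving out the target and locus lists. Every measured gene around SPRY4 was named for IT1_del against vo. The design, the gene lists, this rule and the alternatives listed next were fixed before the data were examined.

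Alternatives were DESeq2 1.42.0, RLE factors, library size without factors, no filter on low counts, a filter at 1 CPM in 3 libraries with a total of 100, only the 2 groups compared, the replicate number as a block, removal of mitochondrial and the 10 most abundant other genes, glmTreat against a 1.5-fold change, and each of the 12 libraries left out in turn. The TPM fit was repeated with a pseudocount of 0.1 and without its filter of 1 TPM in 3 samples. Set tests with camera were not run under DESeq2, glmTreat or the TPM fit. Other alternatives were chosen after seeing the data: the summed CPM of 405 olfactory receptor genes as a covariate (centred log2), genes with a mean CPM of at least 5, and leaving out vo replicate 3 with IT1_del replicate 3. A change in a correlation was judged against the SD over its 12 left-out-library values, a rule that replaced a fixed limit of 0.1 after values had been seen.

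Log2 fold changes were also scanned along chromosomes for stretches of at least 20 genes with a mean CPM of at least 5 (10541 genes, values limited to 0.5). The scan followed an exploratory look at chromosomes and bins in which the chromosome 2 stretch had been noticed, and its settings were chosen afterwards. Its p-values come from 200 shuffles of genes, which ignore local co-regulation and cannot go below 0.00498. Lists of MYC growth targets and skeletal muscle genes were chosen after seeing the data. Some results, which need items withheld for evaluation, are not reported here. Unchanged groups were simulated against the vo libraries, with each gene drawn independently, to give the correlation that shared controls produce.

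The count test was tested on simulated data for IT1_del against vo over 22143 genes. The changed genes, 50 at each size, all had a mean CPM of at least 5, so recovery below that level was not measured. The test called 70% of them at 1.25-fold, 96% at 1.5-fold, 100% at 2-fold and 100% at 4-fold. Of its 200 calls, 17 were false (8.5%). Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.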

Results

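RNA sequencing libraries were made from CHLA-01-MED (CHLA01), an established human cell line from a Group 4 medulloblastoma, an embryonal tumour of the cerebellum. The series concerns SPRIGHTLY, a long non-coding RNA formerly called SPRY4-IT1 that is transcribed from an intron of SPRY4. It also concerns PTBP1, an RNA-binding repressor of exon inclusion, and SMYD3, a lysine methyltransferase. The 12 libraries came from 4 lines with 3 replicates each. The line vo, an abbreviation the labels do not explain, carried no named edit or added gene and served as the reference. In IT1_del, SPRIGHTLY had been reduced with lentiviral Cas9 and a pair of guide RNAs flanking its gene, followed by isolation of single clones. SMYD3_Myc and SMYD3_E5Del_Myc were stable clones carrying plasmids for Myc-tagged SMYD3, either complete or with its exon 5 deleted. Each condition is 1 line, so an edit and the clone that carries it cannot be separated. Nothing in the labels says that replicates are separate cultures, so p-values measure the spread between these samples only, which may be technical.

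Total counts were 17757832 to 18743885 in vo and 17120183 to 20079568 in IT1_del. They were 17801105 to 21130937 in SMYD3_Myc and 15752736 to 17242211 in SMYD3_E5Del_Myc. Of 90517 genes in the deposited table, 73095 had a count and 23374 were tested. A floor of 3 counts corresponded to between 0.142 and 0.190 CPM (counts scaled to library size), which covers counting error only. Replicates of a line differed by a common biological coefficient of variation of 4.34%. The lines also differed in the many genes with a few counts each. The summed CPM of 405 olfactory receptor genes, which encode odour receptors of the nasal epithelium, was 25.1 ± 14.1 in vo, 31.0 ± 20.8 in IT1_del, 25.5 ± 10.6 in SMYD3_Myc and 81.3 ± 17.2 in SMYD3_E5Del_Myc (SD, n = 3 each). Each SMYD3_E5Del_Myc library had a higher value (67.6 to 101) than each of the other libraries (12.5 to 55.0). Mitochondrial genes took 2.37% ± 0.15 of counts in vo, 3.01% ± 0.17 in IT1_del, 2.73% ± 0.16 in SMYD3_Myc and 2.65% ± 0.20 in SMYD3_E5Del_Myc (SD, n = 3 each).

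**Figure D1:**
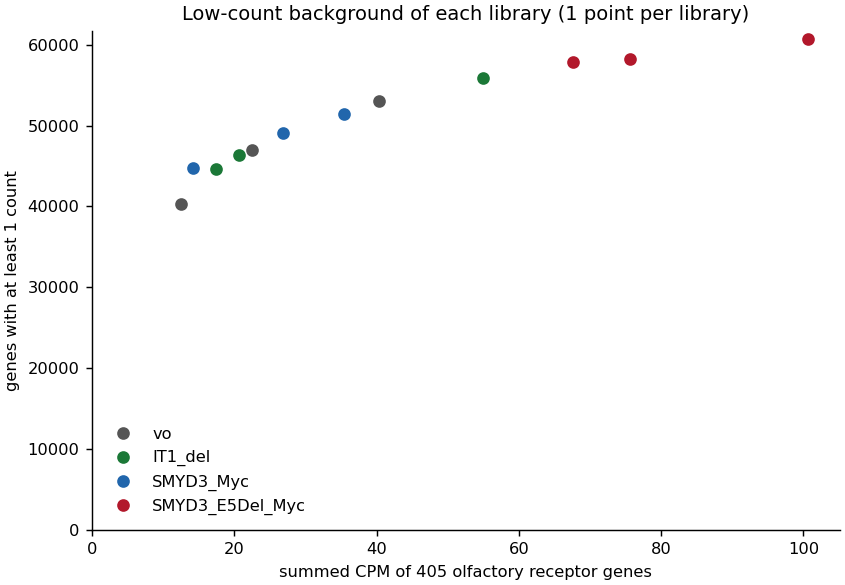
Number of genes with at least 1 count on the y axis against the summed CPM of 405 olfactory receptor genes on the x axis, 1 point per library and 1 colour per line. The SMYD3_E5Del_Myc libraries sit at 67.6 to 101 CPM with 57899 to 60670 genes, while the other 9 lie at 12.5 to 55.0 CPM with 40359 to 55937 genes.

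SMYD3 (ENSG00000185420.18, GRCh38 chromosome 1, 245749342 to 246507312, minus strand in GENCODE 29) had 48.5 ± 3.04 CPM in vo, 44.7 ± 0.82 in IT1_del, 9772 ± 335 in SMYD3_Myc and 3558 ± 166 in SMYD3_E5Del_Myc (SD, n = 3 each). It was 194-fold higher in SMYD3_Myc and 67.6-fold higher in SMYD3_E5Del_Myc than in vo (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p = 1.84e-38 and 2.74e-36). Counts per gene do not separate the plasmid transcript from the endogenous one, nor exon 5 from the rest. The labels do not say which transcript numbers the exons. In GENCODE 29, exon 5 of SMYD3-214, which has 12 exons, spans 137 bp (chromosome 1, 246327201 to 246327337). In IT1_del, SMYD3 differed from vo by less than the test's threshold (log2 fold change −0.13, adjusted p = 0.114), although it was called lower when vo replicate 3 was left out (−0.22, adjusted p = 0.0109).

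SPRY4 (ENSG00000187678.9, chromosome 5, 142310427 to 142326455, minus strand) encodes an inhibitor of receptor tyrosine kinase signalling and hosts SPRIGHTLY. It had 49.1 ± 2.41 CPM in vo, 39.0 ± 2.27 in IT1_del, 79.2 ± 5.19 in SMYD3_Myc and 76.8 ± 4.00 in SMYD3_E5Del_Myc (SD, n = 3 each). It fell in IT1_del (log2 fold change −0.34 ± 0.06 SE, edgeR adjusted p = 0.000115) and rose in SMYD3_Myc (0.64 ± 0.06, 6.5e-10) and SMYD3_E5Del_Myc (0.53 ± 0.06, 2.49e-08). SPRIGHTLY itself has no entry under its symbol in the deposited tables and was not analysed here, so the reduction named by the IT1_del label was not checked. PTBP1 (ENSG00000011304.19, chromosome 19, 797075 to 812327, plus strand) had 167 ± 5.84 CPM in vo, 178 ± 14.1 in IT1_del, 170 ± 7.86 in SMYD3_Myc and 165 ± 3.29 in SMYD3_E5Del_Myc (SD, n = 3 each). It passed no test in IT1_del (0.08, adjusted p = 0.353) or SMYD3_Myc (−0.03, adjusted p = 0.765). Leaving out IT1_del replicate 3 gave a call in IT1_del (0.15, adjusted p = 0.0362). Its call in SMYD3_E5Del_Myc (−0.14 ± 0.05 SE, adjusted p = 0.0436) was lost without any 1 of the 3 vo or 3 SMYD3_E5Del_Myc libraries, IT1_del replicate 1 or 2, or SMYD3_Myc replicate 2 (adjusted p 0.0595 to 0.449). CPM values here are scaled by library size and fold changes by TMM factors (trimmed mean of M-values), which is why the PTBP1 fold change exceeds the difference in CPM.

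**Figure D2:**
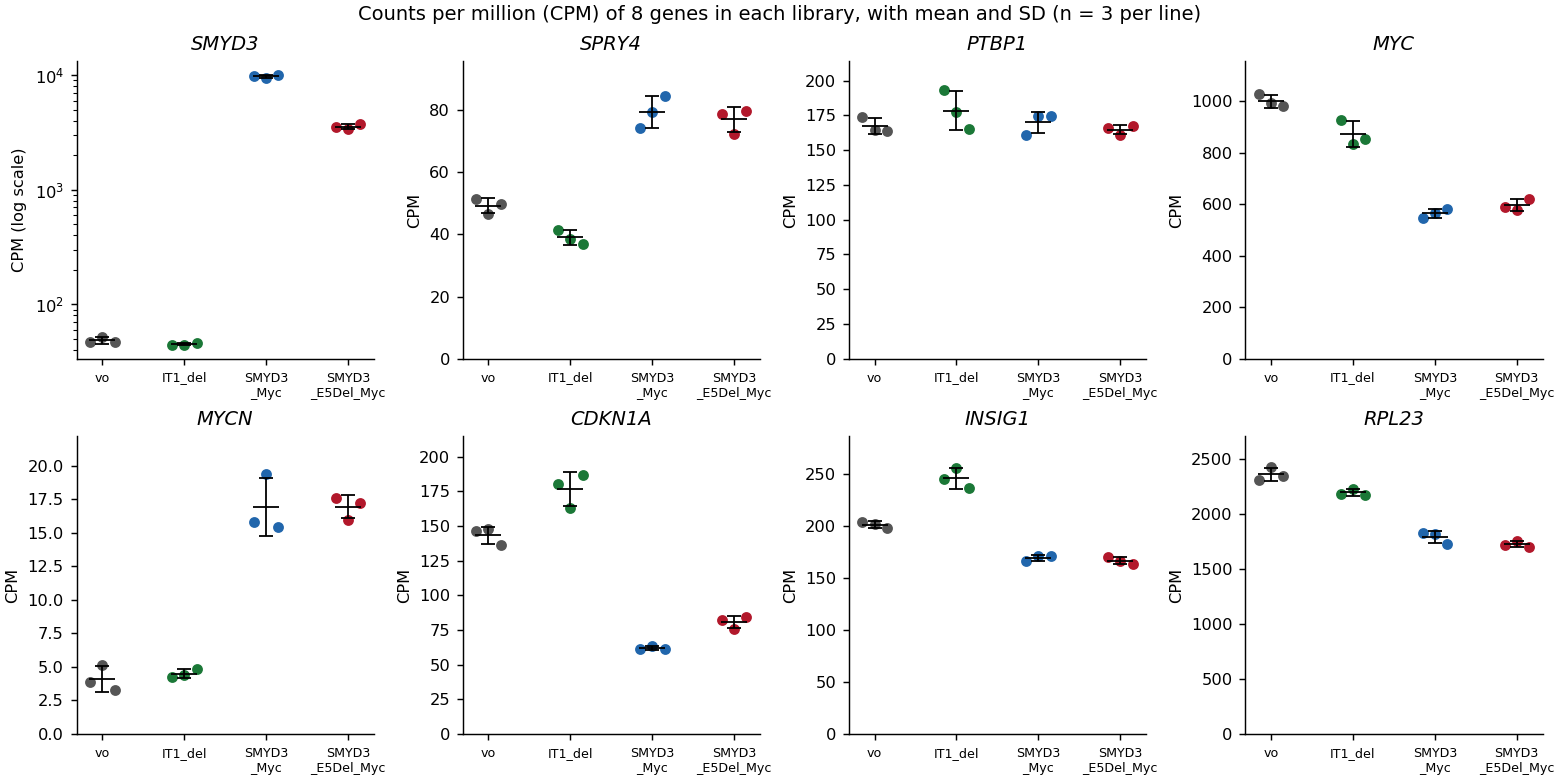
CPM of SMYD3 (log axis), SPRY4, PTBP1, MYC, MYCN, CDKN1A, INSIG1 and RPL23 on the y axes for the 4 lines on the x axes, with 1 point per library and the mean and SD over 3 libraries. SMYD3 reached 9772 CPM in SMYD3_Myc and 3558 in SMYD3_E5Del_Myc against 48.5 in vo, and MYC was lower in both SMYD3 lines (565 and 596 CPM) than in vo (999).

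The comparison of IT1_del with vo asked which genes differed in the line with reduced SPRIGHTLY. UGT8, which makes the myelin lipid galactosylceramide, rose from 0.146 ± 0.16 CPM in vo to 26.2 ± 1.58 in IT1_del (SD, n = 3 each), or from 8 to 1441 counts, a ratio of 179 (95% counting interval 90.6 to 415). PREX2, an activator of the small GTPase Rac, rose 131-fold, and MMP16, a membrane-bound matrix protease, 83.1-fold. MEF2C, a transcription factor of muscle and neurons, rose 61.1-fold and FIRRE, a nuclear long non-coding RNA, 28.4-fold (edgeR adjusted p 6.82e-26 to 3.29e-21). CDH26, a cadherin, fell from 69.1 ± 4.58 to 1.08 ± 0.20 CPM. TPH2, the neuronal enzyme that starts serotonin synthesis, fell from 13.1 ± 1.23 to 0.27 ± 0.20 CPM. ELAPOR1, a lysosomal protein, fell from 15.6 ± 0.46 to 0.74 ± 0.30, and C22orf34, whose role is not given in the sources used here, from 17.8 ± 1.45 to 0.99 ± 0.17 (SD, n = 3 each; adjusted p 3.1e-28 to 2.46e-19). Values of 3 further genes are uncertain because near-identical copies share their reads. SPRR2F, a protein of the cornified envelope, rose with a log2 fold change of 7.08. The zinc finger genes ZNF492 (901 to 4 counts, ratio 227, 95% counting interval 88.2 to 834) and ZNF730 (649 to 8 counts, ratio 81.7, interval 41.2 to 190) fell.

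Around SPRY4 on chromosome 5, 1 of 12 measured genes rose, 4 fell and 7 did not pass, and the counts were the same when adjusted over the list alone (camera adjusted p = 0.116). The fry test, which asks only whether a list's own genes move 1 way, passed this list (adjusted p = 0.000463). FGF1, a growth factor (142592178 to 142698070), fell with a log2 fold change of −1.42 ± 0.23 SE (edgeR adjusted p = 1.7e-05). ARHGAP26, a GTPase-activating protein (142770377 to 143229011), fell with −0.65 ± 0.09 (6.24e-07) and NDFIP1, an adaptor of ubiquitin ligases (142108505 to 142154443), with −0.21 ± 0.04 (0.000477). NR3C1, the glucocorticoid receptor (143277931 to 143435512), rose (0.59 ± 0.10, 6.78e-05). GNPDA1, RNF14, PCDH1, PCDH12, DELE1 and KCTD16 did not pass, nor did SPRY4-AS1 (−0.06, adjusted p = 0.958). SPRY4-AS1 lies on the strand opposite SPRY4 and its counts are uncertain because the strand setting of the counting is not stated. List members named because 5 or fewer were called were chosen after their values were seen, in this and the other comparisons. Among 9 measured genes around SMYD3 on chromosome 1, SCCPDH (−0.69) and CNST (−0.16) were among those that fell. The camera adjusted p was 0.0207 (adjusted p = 0.267 with an estimated correlation), and 0.0803 with the preset one but without IT1_del replicate 3.

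Genes of cholesterol synthesis and its control rose in IT1_del. Of 22 genes, 16 rose and 6 did not pass (17 rose when adjusted over the list alone; camera adjusted p = 1.3e-08, adjusted p = 0.267 with an estimated correlation). SREBF2, the transcription factor of the pathway, rose by 0.39 ± 0.05 SE, STARD4, a sterol carrier, by 0.42 ± 0.06, and INSIG1, its feedback inhibitor, by 0.28 ± 0.04 on the log2 scale (edgeR adjusted p 9.46e-08 to 8.7e-06). Of 25 targets of the tumour suppressor p53, 9 rose and 16 did not pass, the same number when adjusted over the list alone. The camera adjusted p was 0.0207 (adjusted p = 0.314 with an estimated correlation, and 0.136 without vo replicate 3 or 0.0986 without IT1_del replicate 1). FDXR (0.53), PHLDA3 (0.49), BAX (0.34) and CDKN1A, an inhibitor of cyclin-dependent kinases (0.29), were among them (adjusted p 2.15e-05 to 0.000205). Mitochondrially encoded genes had 4 of 13 rising, MT-CO3 (0.36), MT-CO1 (0.32), MT-CO2 (0.32) and MT-ND4 (0.36). When adjusted over the list alone, 8 rose (camera adjusted p = 0.00375, adjusted p = 0.492 with an estimated correlation). MT-ND4 lost its call without vo replicate 2 (adjusted p = 0.0805) or IT1_del replicate 3 (0.0884).

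A further 5 lists had a camera adjusted p = 0.0486 in IT1_del, which library-size scaling raised to 0.0613 and leaving out IT1_del replicate 3 to 0.0803 or more. Markers of the sonic hedgehog type of medulloblastoma had 5 of 12 rising (5 when adjusted over the list alone): SFRP1, a WNT antagonist (0.68 ± 0.06 SE, edgeR adjusted p = 7.9e-11), PDLIM3 (0.50 ± 0.05, 6.06e-10), GLI2, PTCH1 and BOC. The calls of GLI2 (0.74, adjusted p = 0.0103) and BOC (0.25, adjusted p = 0.0106) were lost without single libraries. For GLI2 these were vo replicate 1 (0.0865) or IT1_del replicate 3 (0.0882). For BOC they were vo replicate 2 (0.0644) or 3 (0.146) or IT1_del replicate 1 (0.126) or 2 (0.0571). Glial markers had 2 of 13 rising and 1 falling, with the same counts when adjusted over the list alone. PDGFRA, a growth factor receptor (1.08 ± 0.06, 4.42e-15), and CSPG4 (0.61 ± 0.13, 0.000643) rose. The 1 that fell was SLC1A3, a glutamate transporter (−0.16 ± 0.04, 0.00358, but 0.0502 without vo replicate 2). Among 21 interferon response genes, HERC5 (2.89), IRF7 (1.28) and IFI35 (0.41) rose. Mesenchymal and matrix genes had 8 of 28 rising and 1, CDH2, falling (−0.20), and abundant non-coding RNAs had 1 of 3 rising, NEAT1 (log2 fold change 0.60). With an estimated correlation these lists had adjusted p = 0.267 for sonic hedgehog markers, adjusted p = 0.267 for glial markers, adjusted p = 0.5 for interferon genes, adjusted p = 0.349 for mesenchymal genes and adjusted p = 0.267 for non-coding RNAs. Genes of axon guidance and adhesion moved both ways, 16 up and 11 down of 42, with a median of 0.26 and a mean of −0.00 (camera adjusted p = 0.743). The other lists named here did not pass camera, which compares a list with all other genes. Feedback genes of the ERK kinases had 21 members, with ETV5 and DUSP5 up and SPRY4, DUSP4, DUSP6 and SHC4 down (camera adjusted p = 0.868). The EGF receptor pathway had 8 of 41 up, and EGFR, ERBB3 and STAT3 were among those down (0.24). Splicing regulators had 9 up and 7 down of 49 (0.944). Cell cycle genes had 3 up, AURKB, CENPE and RRM2, and 8 down of 46 (0.116). Ribosomal proteins had 2 up, RPL37A and RPS2, and 6 down of 37 (0.171). Of 12 markers of Group 4, RBM24, BARHL2, TBR1, SNCAIP and ERBB4 rose and MEIS2 fell (0.148). The fry test, which asks only whether a list's own genes move 1 way, passed Group 4 markers (up, adjusted p = 0.000529) but none of these other lists (0.0768 or more).

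Genome-wide, 2063 genes were higher and 2071 lower in IT1_del than in vo, with 352 and 331 of them changing at least 2-fold. The count of higher genes was 1286 without vo replicate 1, 1297 without IT1_del replicate 1 and 1349 without IT1_del replicate 2. In a stretch of chromosome 2 (GRCh38, 170813213 to 227718031), singled out after the values were seen, 141 of 194 genes with a mean CPM of at least 5 were called higher and 10 lower, with a median log2 fold change of 0.29. List tests of IT1_del were not repeated without the genes of this stretch, so its share in their results is open.

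**Figure D3:**
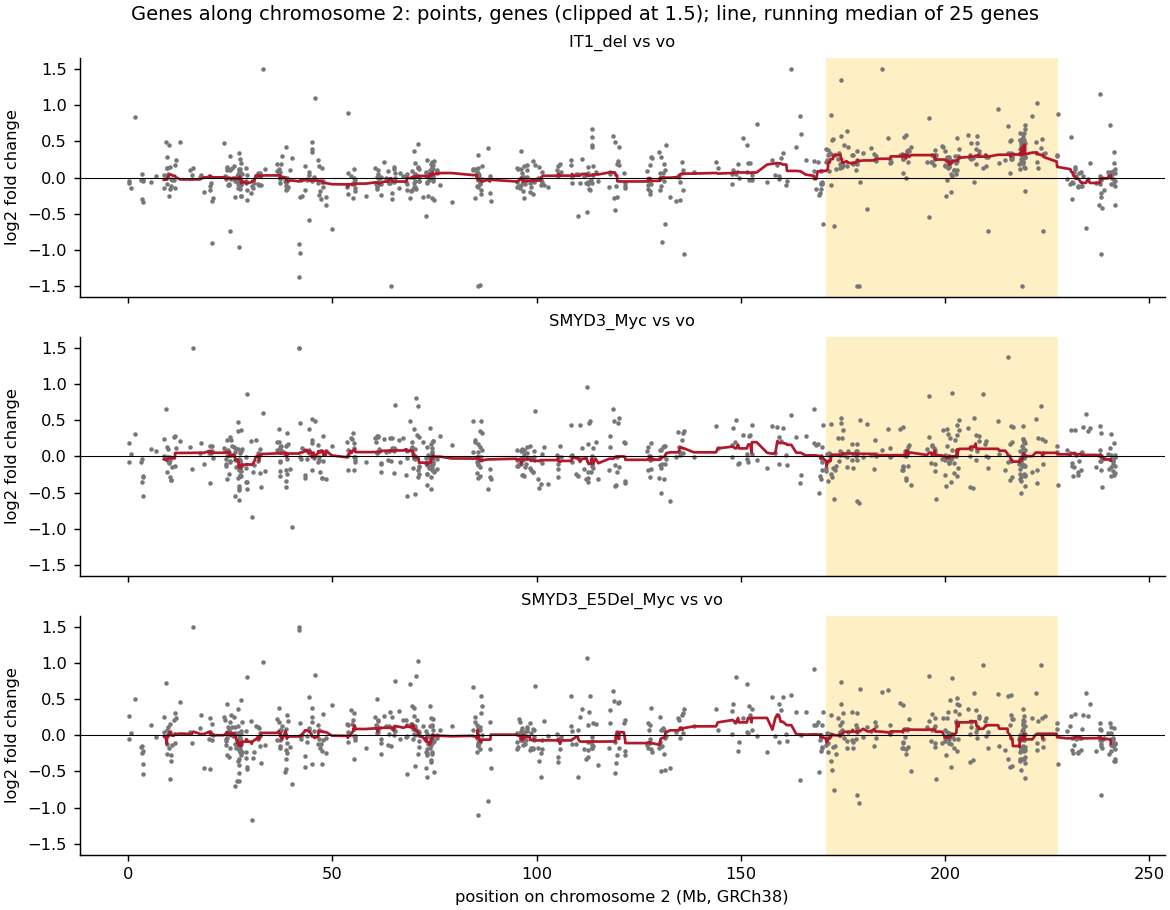
Log2 fold change against vo on the y axis by position in Mb along chromosome 2 on the x axis for IT1_del, SMYD3_Myc and SMYD3_E5Del_Myc, with 1 point per gene with a mean CPM of at least 5 (limited to 1.5) and a running median of 25 genes as a line. In the shaded stretch from 170.81 to 227.72 Mb the median is 0.29 in IT1_del, 0.02 in SMYD3_Myc and 0.02 in SMYD3_E5Del_Myc.

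The comparison of SMYD3_Myc with vo asked what accompanied added complete SMYD3. CNTN2, an axonal adhesion molecule, rose 6.40-fold (2.77 ± 0.51 to 18.4 ± 1.72 CPM). MYCN, a transcription factor amplified in some medulloblastomas, rose 3.97-fold (4.10 ± 0.98 to 16.9 ± 2.16 CPM). PDGFRA rose 3.77-fold (18.5 ± 0.92 to 72.4 ± 3.67 CPM), COL27A1, a fibrillar collagen, 3.51-fold and C2orf91, whose role is not given in the sources used here, 3.36-fold (SD, n = 3 each; edgeR adjusted p 1.9e-21 to 2.73e-08). CDKN1A fell from 143 ± 6.17 to 62.0 ± 1.38 CPM (log2 fold change −1.26 ± 0.05 SE, adjusted p = 1.04e-16). The complement component C7 fell with a log2 fold change of −1.71, PARP10, an ADP-ribosyltransferase, with −1.41 and EMP3, a membrane protein, with −1.34. CKM, the creatine kinase of muscle, fell with −1.29 and MYOD1, the transcription factor that starts muscle differentiation, with −1.22 (adjusted p 2.24e-12 to 3.29e-07). CKM and MYOD1 were also called lower in SMYD3_E5Del_Myc and in IT1_del against vo.

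Ribosomal protein genes fell in SMYD3_Myc. Of 37 genes, 36 fell and 1 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 1.04e-17, adjusted p = 0.214 with an estimated correlation). Their median log2 fold change was −0.26 relative to all genes with a mean CPM of at least 5. RPL23 (−0.45 ± 0.04 SE), RPL38 (−0.42 ± 0.04), RPL18 (−0.42 ± 0.04) and RPL11 (−0.41 ± 0.04) were among them (edgeR adjusted p 1.25e-10 to 8.88e-10), although reads of these genes can be shared with processed pseudogenes. Of 27 targets of ATF4 and the unfolded protein response, 16 fell, 2, PHGDH and ATF4, rose and 9 did not pass (17 and 2 when adjusted over the list alone; camera adjusted p = 9.83e-07, adjusted p = 0.199 with an estimated correlation). The endoplasmic reticulum chaperones PDIA4 (−0.57), MANF (−0.55) and HSP90B1 (−0.43) and the amino acid transporter subunit SLC3A2 (−0.54) fell. Cholesterol genes went down, with 14 of 22 falling, 1 rising and 7 not passing (20 and 1 when adjusted over the list alone; camera adjusted p = 9.83e-07, adjusted p = 0.199 with an estimated correlation). The enzymes HMGCS1 (−0.40), DHCR7 (−0.38) and FDPS (−0.36) fell, and the 1 that rose was SREBF2 (0.33 ± 0.05 SE, adjusted p = 1.8e-06). Of 25 p53 targets, 14 fell, 2, GADD45A and TP53INP1, rose and 9 did not pass (17 and 3 when adjusted over the list alone; camera adjusted p = 6.15e-06, adjusted p = 0.156 with an estimated correlation). DDB2 (−0.63) and AEN (−0.62), which act in DNA repair and apoptosis, and the death receptor TNFRSF10B (−0.57) fell beside CDKN1A.

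Feedback genes of the ERK kinases rose in SMYD3_Myc. Of 21 genes, 11 rose, 1 fell and 9 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 9.83e-07, adjusted p = 0.013 with an estimated correlation). IL17RD, an inhibitor of fibroblast growth factor signalling, rose 3.97-fold, ETV5, a transcription factor induced by ERK, 1.94-fold, KLF10 1.64-fold and SPRY4 1.56-fold (edgeR adjusted p 5.93e-13 to 6.5e-10). The 1 that fell was SPRY1 (−0.71 ± 0.11 SE, adjusted p = 9.86e-06). Cell cycle genes had 25 of 46 rising and 9 falling (26 and 10 when adjusted over the list alone; camera adjusted p = 0.000387, adjusted p = 0.474 with an estimated correlation). Axon guidance and adhesion genes had 14 of 42 rising and 5, UNC5B, SEMA3C, PLXNA4, NRCAM and EPHA4, falling (16 and 7; 0.00989, adjusted p = 0.213 with an estimated correlation). Neuronal differentiation genes had 11 of 38 rising and 6 falling (12 and 6; 0.0143, adjusted p = 0.216 with an estimated correlation). Mitochondrially encoded genes had 7 of 13 rising (7; 0.00085, adjusted p = 0.362 with an estimated correlation). The EGF receptor pathway had 9 of 41 rising and 4, ERBB3, ERRFI1, NRG2 and NRAS, falling (camera adjusted p = 0.0143, adjusted p = 0.362 with an estimated correlation). The p was 0.0621 without vo replicate 3 and 0.0639 without SMYD3_Myc replicate 3, and 16 of 37 rose in a fit of genes with a mean CPM of at least 5. Of 11 measured genes reported as SMYD3 targets elsewhere, MYC fell from 999 ± 24.3 to 565 ± 17.5 CPM (SD, n = 3 each; log2 fold change −0.88 ± 0.04 SE, adjusted p = 3.18e-15). CTNNB1 (0.40) and JAK1 (0.47) rose and 8 did not pass (camera adjusted p = 0.884). That list did not pass camera in SMYD3_E5Del_Myc (0.453), where its genes moved both ways, or in IT1_del (0.279), where CCNA1 and MYC fell (4 genes without vo replicate 3). The fry test passed it in IT1_del (adjusted p = 0.00261). Markers of the sonic hedgehog type had MYCN, ZIC2, GLI2 and BOC rising and PDLIM3 falling of 12 (camera adjusted p = 0.0447, adjusted p = 0.199 with an estimated correlation). Their call was lost without vo replicate 1 (0.061) or SMYD3_Myc replicate 3 (0.0588). Group 4 markers had GFI1, UNC5D and KDM6A rising and RBM24 falling of 12 (camera adjusted p = 0.0449, adjusted p = 0.199 with an estimated correlation). Their call was lost without vo replicate 2 (0.0969), IT1_del replicate 1 (0.0519) or 3 (0.0545), SMYD3_Myc replicate 1 (0.0753) or 2 (0.0743), or SMYD3_E5Del_Myc replicate 3 (0.0563). Glial markers had PDGFRA, OLIG1, OLIG2 and SLC1A2 rising and SLC1A3 falling of 13 (camera adjusted p = 0.0449, adjusted p = 0.213 with an estimated correlation). Their call was lost without vo replicate 2 (0.0899) or 3 (0.0586), IT1_del replicate 2 (0.0508) or 3 (0.0539), SMYD3_Myc replicate 1 (0.0918) or 2 (0.0551), or SMYD3_E5Del_Myc replicate 1 (0.0569) or 3 (0.0563).

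Genome-wide, 1999 genes were higher and 3487 lower in SMYD3_Myc than in vo, a split that was 2367 and 2639 with RLE (relative log expression) factors and 2671 and 2650 among genes with a mean CPM of at least 5. The count of lower genes was 1869 without vo replicate 1, 1967 without vo replicate 2 and 1983 without SMYD3_Myc replicate 2.

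The comparison of SMYD3_E5Del_Myc with vo asked what accompanied the form without exon 5. CNTN2 rose 8.04-fold (2.77 ± 0.51 to 24.3 ± 2.17 CPM), IL17RD 5.08-fold (1.84 ± 0.13 to 10.2 ± 0.76 CPM), and COL27A1 5.05-fold (SD, n = 3 each). PDGFRA rose 4.43-fold (to 89.0 ± 1.45 CPM, SD, n = 3) and MYCN 3.82-fold (edgeR adjusted p 5.33e-23 to 2.01e-10). MYOD1 fell with a log2 fold change of −2.03 ± 0.18 SE, C7 with −1.67 ± 0.13 and KLRG2, whose role is not given in the sources used here, with −1.63 ± 0.14. PARP10 fell with −1.60 ± 0.13, S100A16, a calcium-binding protein, with −1.59 ± 0.06 and EMP3 with −1.57 ± 0.11 (adjusted p 8.08e-20 to 1.59e-10). MYC fell to a mean of 596 CPM (−0.86 ± 0.05 SE, adjusted p = 3.29e-15).

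Each of the 37 ribosomal protein genes fell in SMYD3_E5Del_Myc, with the same count when adjusted over the list alone (camera adjusted p = 4.18e-23, adjusted p = 0.247 with an estimated correlation). The median was −0.39 relative to all genes with a mean CPM of at least 5, and RPS18 (−0.63), RPL23 (−0.57), RPL11 (−0.54) and RPS24 (−0.54) were among them (edgeR adjusted p 6.03e-13 to 3.01e-12). ERK feedback genes had 11 of 21 rising, 1 falling and 9 not passing, with the same counts when adjusted over the list alone (camera adjusted p = 2.47e-05, adjusted p = 0.0243 with an estimated correlation). DUSP6, a phosphatase that inactivates ERK, rose 3.21-fold, ETV5 1.96-fold and KLF10 1.51-fold, while SPRY1 fell (−0.51 ± 0.11 SE, adjusted p = 0.000535). Axon guidance and adhesion genes had 21 of 42 rising and 6 falling (25 and 6 when adjusted over the list alone; camera adjusted p = 0.000786, adjusted p = 0.247 with an estimated correlation). PLXNA2, a semaphorin receptor, rose 2.82-fold, UNC5C, a netrin receptor, by a log2 value of 0.88 ± 0.08 SE and RELN, a secreted guide of neuronal migration, by 0.75 ± 0.05. The adhesion molecule NRCAM fell (−0.43 ± 0.04). Of 27 ATF4 and unfolded protein genes, 15 fell and 3, SLC7A11, CHAC1 and PHGDH, rose (17 and 3 when adjusted over the list alone; camera adjusted p = 0.000227, adjusted p = 0.285 with an estimated correlation). PDIA4 (−0.58), SLC3A2 (−0.52), DDIT4 (−0.48) and HSP90B1 (−0.47) fell. Of 25 p53 targets, 15 fell and 4, FAM111A, GADD45A, TP53INP1 and PMAIP1, rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.00162, adjusted p = 0.247 with an estimated correlation). CDKN1A (−0.95), DDB2 (−0.60), AEN (−0.58) and TNFRSF10B (−0.57) fell.

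Neuronal differentiation genes had 15 of 38 rising and 5, CHGA, NEFH, INA, NEFM and NEFL, falling in SMYD3_E5Del_Myc (camera adjusted p = 0.00651, adjusted p = 0.247 with an estimated correlation). Glial markers had 6 of 13 rising and 1, SLC1A3, falling (0.0146, adjusted p = 0.247 with an estimated correlation). Mitochondrially encoded genes had 8 of 13 rising and 2, MT-CO1 and MT-CO2, falling (0.0148, adjusted p = 0.52 with an estimated correlation). Cholesterol genes had 10 of 22 falling and 1, SREBF2, rising (12 and 1 when adjusted over the list alone; camera adjusted p = 0.00651, adjusted p = 0.333 with an estimated correlation). Their median was −0.01 relative to all genes with a mean CPM of at least 5 and the call was lost with library-size scaling (adjusted p = 0.184). Hypoxia and glycolysis genes had 16 of 29 falling and 4, EGLN3, BNIP3L, PFKFB3 and ALDOA, rising (17 and 6 when adjusted over the list alone; camera adjusted p = 0.0233, adjusted p = 0.328 with an estimated correlation). The p was 0.0647 without SMYD3_E5Del_Myc replicate 2. In a fit of genes with a mean CPM of at least 5, 6 of 22 cholesterol genes, 10 of 25 hypoxia and glycolysis genes and 10 of 21 p53 targets fell. Genome-wide, 3737 genes were higher and 4822 lower than in vo, against 5834 and 2765 with library-size scaling, which moved the median of all genes by 0.12. These counts were 1224 and 2240 with the olfactory receptor sum as a covariate, and 2830 and 2871 among genes with a mean CPM of at least 5. Of the 1823 genes at least 2-fold higher, 1361 had a mean under 1 CPM. The count of higher genes was 2484 without vo replicate 2, and that of lower genes 3094 without vo replicate 1.

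**Figure D4:**
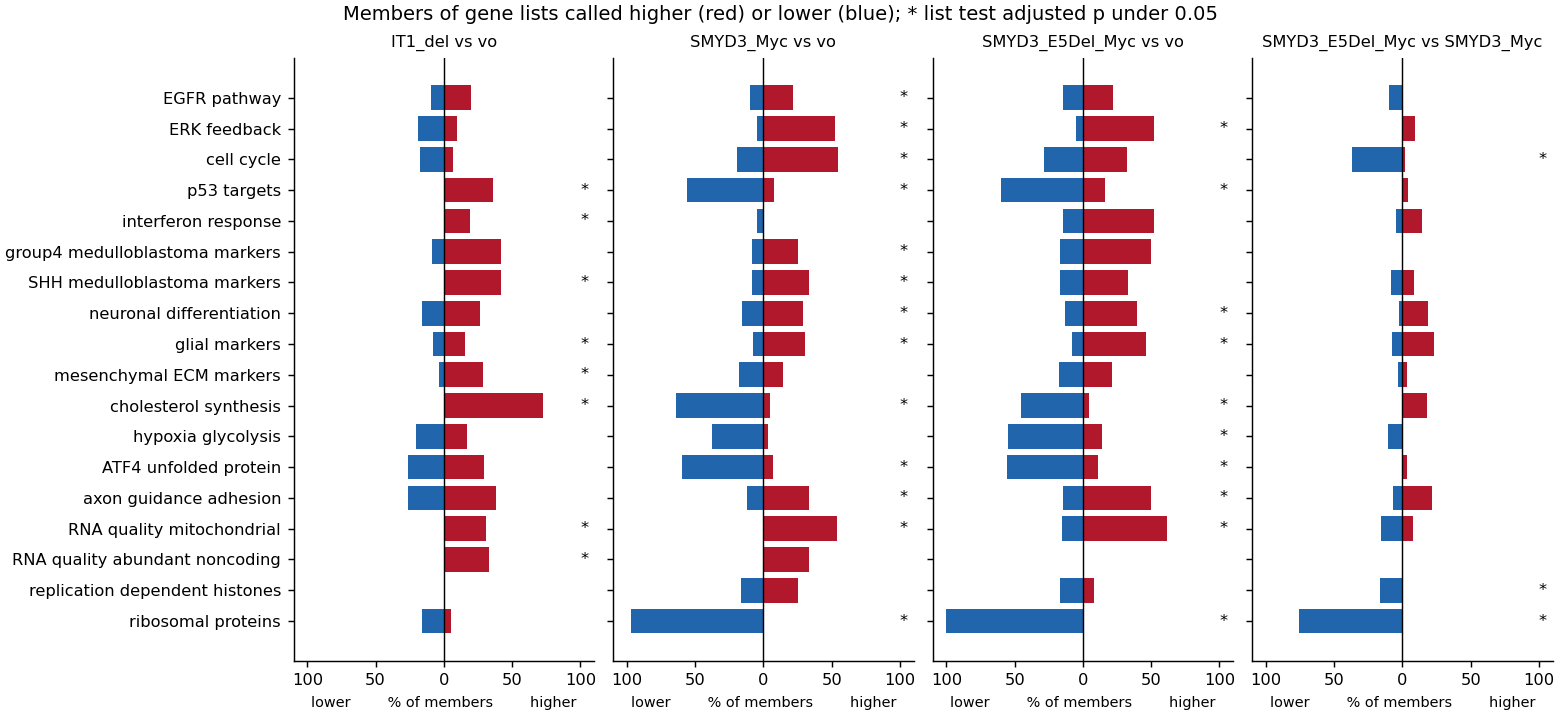
Percent of the measured members of 18 gene lists called higher (red) or lower (blue) on the x axis in 4 comparisons, with an asterisk where the camera adjusted p of the list is under 0.05. Ribosomal protein genes are lower in SMYD3_Myc (36 of 37) and SMYD3_E5Del_Myc (37 of 37) against vo, and cholesterol genes are higher in IT1_del (16 of 22) and lower in SMYD3_Myc (14 of 22).

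The comparison of SMYD3_E5Del_Myc with SMYD3_Myc asked how the line with the shortened form differed from that with the complete one. SMYD3 itself was lower (log2 fold change −1.52 ± 0.04 SE, edgeR adjusted p = 1.66e-21). The lines thus differ in the amount of SMYD3 RNA as well as in its form, and these cannot be told apart here. ATOH8, a transcription factor of the basic helix-loop-helix class, fell from 55.3 ± 1.77 to 28.2 ± 2.80 CPM (SD, n = 3 each; −1.04 ± 0.08 SE, adjusted p = 1.04e-09). PKD2L1, a cation channel, rose from 13.5 ± 0.30 to 23.4 ± 1.16 CPM (0.74 ± 0.08 SE, adjusted p = 2.66e-07). TAFA5, a secreted protein of the nervous system (−1.02), CCNA1, a cyclin of the germ line (−1.01), and C1QL1, a secreted synaptic protein (−0.89), fell, and MAGEC2, a cancer-testis antigen, rose (0.76) (adjusted p 3.97e-06 to 0.000894). The small non-coding RNA RNY1 fell (−1.09 ± 0.20 SE, adjusted p = 0.00954), a call lost without SMYD3_E5Del_Myc replicate 1 (adjusted p = 0.052) or 2 (0.0704). MAPK10, a stress kinase of neurons (0.77), PTCHD4, a patched-related protein (0.69), and SYNE1, a protein of the nuclear envelope (1.02), rose too. ADAMTS9-AS2, an antisense RNA whose counts depend on the unstated strand setting, rose 2.14-fold, a call lost without SMYD3_E5Del_Myc replicate 2 (adjusted p = 0.0558). With the olfactory receptor sum as a covariate the adjusted p values of MAPK10, PTCHD4, ADAMTS9-AS2 and SYNE1 were 0.805, 0.375, 0.936 and 0.97. SYNE1 also lost its call without vo replicate 1, IT1_del replicate 2, SMYD3_E5Del_Myc replicate 2 or 3, or any 1 of the 3 SMYD3_Myc libraries (adjusted p up to 0.157). SPRY4 (−0.11, adjusted p = 0.234) and PTBP1 (−0.11, adjusted p = 0.213) did not pass, though both were called without IT1_del replicate 3 (0.0443 and 0.0179) or SMYD3_Myc replicate 1 (0.0374 and 0.0399).

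Ribosomal protein genes were lower still in SMYD3_E5Del_Myc. Of 37 genes, 28 fell and 9 did not pass (35 fell when adjusted over the list alone; camera adjusted p = 1.14e-15, adjusted p = 0.515 with an estimated correlation). Examples are RPLP1 (−0.27 ± 0.05 SE), RPL13A (−0.27 ± 0.04), RPL4 (−0.23 ± 0.04) and RPS19 (−0.23 ± 0.05). Cell cycle genes had 17 of 46 falling and 1, RRM2, rising (22 and 1 when adjusted over the list alone; camera adjusted p = 1.99e-07, adjusted p = 0.515 with an estimated correlation). CENPA, the histone of centromeres (−0.39 ± 0.06 SE), the mitotic kinesins KIF23 (−0.25 ± 0.04) and KIF20A (−0.24 ± 0.04) and the checkpoint kinase BUB1 (−0.22 ± 0.04) fell. With the olfactory receptor sum as a covariate, edgeR gave these ribosomal and cell cycle genes adjusted p values from 0.114 (KIF23) to 0.653 (RPS19). Of 12 histone genes H4C11 (−0.29) and H4C2 (−0.37) fell and 10 did not pass (camera adjusted p = 0.0259, adjusted p = 0.537 with an estimated correlation). The p was 0.0671 without SMYD3_Myc replicate 2 and 0.053 without SMYD3_E5Del_Myc replicate 2. In a fit of genes with a mean CPM of at least 5, fewer ribosomal protein genes (17 of 37) and cell cycle genes (8 of 44) fell, and more cholesterol genes (9 of 22) rose. Neuronal differentiation genes had 7 of 38 rising and 1, NEUROG1, falling (12 and 2 when adjusted over the list alone; camera adjusted p = 0.0682). Of 22 cholesterol genes 4 rose, HMGCS1 (0.23), STARD4 (0.24), SC5D (0.18) and MSMO1 (0.17) (7 rose and 1 fell when adjusted over the list alone; camera adjusted p = 0.0682). ERK feedback genes had 2 of 21 rising, DUSP6 (0.39) and IL17RD (0.36), and the list did not pass camera (adjusted p = 0.421).

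Genome-wide, 1129 genes were higher and 1011 lower in SMYD3_E5Del_Myc than in SMYD3_Myc, against 1611 and 462 with library-size scaling, and 34 and 62 with the olfactory receptor sum as a covariate. Single libraries moved these counts. Those higher were 1957 without IT1_del replicate 3, 394 and 341 without SMYD3_Myc replicates 2 and 3, and 246 and 609 without SMYD3_E5Del_Myc replicates 2 and 3. Those lower were 666 and 2636 without vo replicates 1 and 2, 2432 without IT1_del replicate 3, 1731 and 358 without SMYD3_Myc replicates 1 and 2, and 455 and 407 without SMYD3_E5Del_Myc replicates 1 and 2.

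Because the series links SPRIGHTLY to SMYD3 exon skipping, the effects of IT1_del and SMYD3_E5Del_Myc were compared with each other, a contrast in which the vo libraries cancel. SPRY4 was lower in IT1_del (log2 fold change −0.87 ± 0.06 SE, edgeR adjusted p = 4.25e-13), as were IL17RD (−2.38 ± 0.15), DUSP6 (−2.34 ± 0.15) and KLF10 (−0.65 ± 0.06). CDKN1A was higher (176 ± 12.3 against 80.7 ± 4.30 CPM, SD, n = 3 each; 1.23 ± 0.05 SE, adjusted p = 9.39e-18), as were DDB2 (0.79) and TNFRSF10B (0.72), and PTBP1 was higher too (0.22 ± 0.05 SE, adjusted p = 0.00159), in a contrast where the median of genes with a mean CPM of at least 5 was 0.10. SRL, a calcium-binding protein of muscle, was 20.0-fold higher in IT1_del. UGT8 (5.83), MMP16 (5.30), PREX2 (4.99) and FIRRE (4.64) were higher and TPH2 (−6.34) and CDH26 (−6.15) lower in IT1_del, the same directions as against vo.

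In that contrast 22 of 22 cholesterol genes were higher in IT1_del, with the same count when adjusted over the list alone (camera adjusted p = 8.29e-10, adjusted p = 0.134 with an estimated correlation). Among them were INSIG1 (0.67), DHCR7 (0.59) and HMGCS1 (0.43). Of 25 p53 targets 18 were higher and 3, FAM111A, GADD45A and TP53INP1, lower, with the same counts when adjusted over the list alone (camera adjusted p = 2.72e-05, adjusted p = 0.134 with an estimated correlation). Of 37 ribosomal protein genes 36 were higher (37 when adjusted over the list alone; camera adjusted p = 3.33e-18, adjusted p = 0.321 with an estimated correlation), for example RPL37A (0.79), RPS18 (0.68), RPL3 (0.60) and RPS14 (0.56). ATF4 and unfolded protein genes had 20 of 27 higher (20 when adjusted over the list alone; camera adjusted p = 2.72e-05, adjusted p = 0.321 with an estimated correlation), including the amino acid transporter SLC7A5 (0.79), the serine pathway enzyme PSAT1 (0.65) and SLC3A2 (0.62). In a fit of genes with a mean CPM of at least 5, 13 of 22 ATF4 and unfolded protein genes were higher. ERK feedback genes had 12 of 21 lower and 2, SPRY1 and DUSP5, higher (camera adjusted p = 0.000378, adjusted p = 0.0732 with an estimated correlation). Hypoxia and glycolysis genes had 15 of 29 higher and 4, EGLN3, BNIP3L, P4HA1 and BNIP3, lower (camera adjusted p = 0.0368, adjusted p = 0.38 with an estimated correlation). Genome-wide, 5211 genes were higher and 3868 lower in IT1_del, against 3404 and 5590 with library-size scaling, which moved the median of all genes by −0.11. With the olfactory receptor sum as a covariate they were 3371 and 2073. The count of higher genes was 3080 without IT1_del replicate 1, 3399 without IT1_del replicate 2 and 3460 without SMYD3_E5Del_Myc replicate 1.

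Log2 fold changes were then correlated across the 23374 genes, which are not independent replicates, in 4 pairs of comparisons. For SMYD3_Myc and SMYD3_E5Del_Myc, both against vo, 1387 genes were higher in both, 3100 lower in both and 12 went opposite ways. Independent lists would share 320 and 719 calls in the same direction. The correlation was r = 0.50 over all genes and 0.87 over genes with a mean CPM of at least 5, while groups simulated without change against the same vo libraries gave 0.50 in both cases. The covariance of those more abundant genes was 0.0729 against 0.00368 simulated. For IT1_del against vo and SMYD3_E5Del_Myc against SMYD3_Myc, which share no library, 123 genes were higher in both, 279 lower in both and 182 opposite (99.6 and 89.6 expected), with r = 0.25 (Spearman 0.19). This r was 0.09 with DESeq2, 0.07 with limma on log2(TPM + 1) and 0.07 without a filter on low counts. Over genes with a mean CPM of at least 5 it was 0.18. With the olfactory receptor sum as a covariate it was 0.18, and without vo replicate 3 and IT1_del replicate 3 it was 0.16. The r was −0.14 without IT1_del replicate 3, 0.09 without vo replicate 2 and 0.48 without vo replicate 3. IT1_del against vo had r = 0.25 with SMYD3_Myc against vo (simulated 0.51, 449 higher in both, 627 lower in both, 714 opposite; 176 and 309 expected). It had r = 0.37 with SMYD3_E5Del_Myc against vo (simulated 0.50, 550 higher in both, 861 lower in both, 773 opposite; 330 and 427 expected). Over genes with a mean CPM of at least 5 these correlations were 0.07 and 0.15 (simulated 0.50 in both cases). The covariances over all genes were above the simulated ones, 0.0562 against 0.0351 with SMYD3_Myc and 0.136 against 0.0349 with SMYD3_E5Del_Myc. The simulation drew each gene independently, without the low-count background that differs between libraries of a line. A covariance above the simulated one therefore does not alone show a shared effect. With vo replicate 3 left out, the correlations of IT1_del with these lines over all genes were 0.59 and 0.67, and that of the SMYD3 lines was 0.76. Without IT1_del replicate 3 the value of IT1_del and SMYD3_E5Del_Myc was 0.00262, and without SMYD3_Myc replicate 1 that of the SMYD3 lines was 0.20. The 3 vo libraries are too few to be split between comparisons, so part of each correlation against vo may come from shared controls. Expected numbers were computed for calls in the same direction only. None was computed for opposite calls, so an excess over the expected numbers does not alone show agreement.

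**Figure D5:**
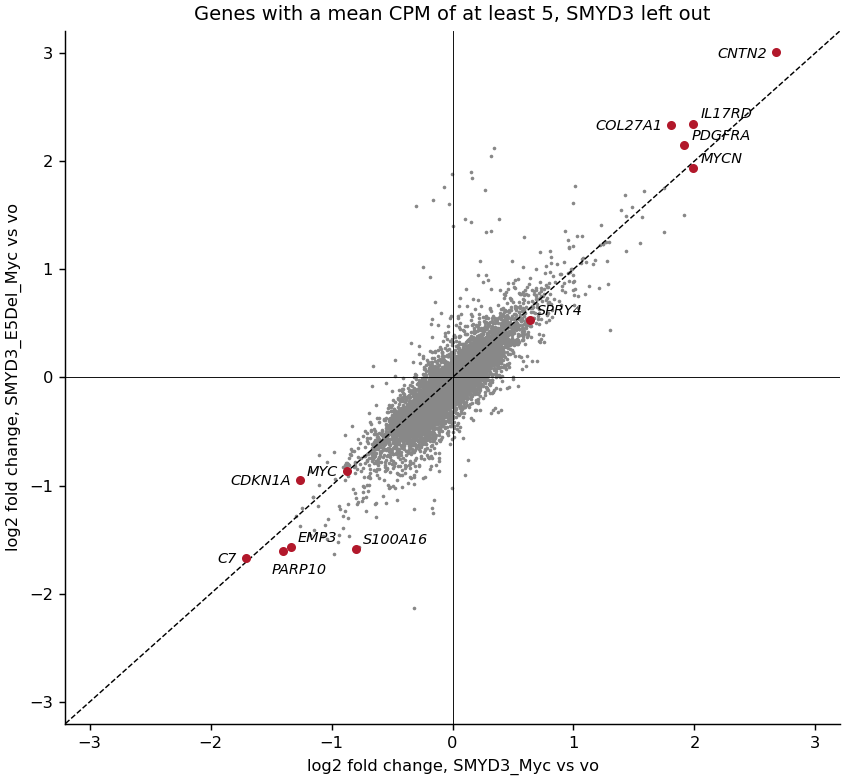
Log2 fold change of SMYD3_E5Del_Myc against vo on the y axis by that of SMYD3_Myc against vo on the x axis, 1 point for each of 11248 genes with a mean CPM of at least 5 (SMYD3 left out), with a dashed line where both are equal. MYCN (1.99 and 1.93) and MYC (−0.88 and −0.86) lie near the line, and CNTN2 (2.68 and 3.01) and CDKN1A (−1.26 and −0.95) above it.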

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

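The contrast of IT1_del with SMYD3_E5Del_Myc was chosen before the data were examined, and these 3 results were picked from it after their values were seen. Each was called in opposite directions in the 2 lines against vo, for the lists only with the preset correlation, and the difference itself was tested.

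Of 25 p53 targets, 9 rose in IT1_del, while 15 fell and 4 rose in SMYD3_E5Del_Myc. In IT1_del the list had a camera adjusted p = 0.0207 (adjusted p = 0.314 with an estimated correlation; 0.136 without vo replicate 3 and 0.0986 without IT1_del replicate 1). In SMYD3_E5Del_Myc it had 0.00162 (adjusted p = 0.247 with an estimated correlation). The difference had a camera adjusted p = 2.717e-05 (adjusted p = 0.134 with an estimated correlation). Of 22 cholesterol genes, 16 rose in IT1_del, while 10 fell and 1 rose in SMYD3_E5Del_Myc. Against vo their camera adjusted p was 1.3e-08 in IT1_del (adjusted p = 0.267 with an estimated correlation) and 0.00651 in SMYD3_E5Del_Myc (adjusted p = 0.333 with an estimated correlation), where the median was −0.01 relative to all genes with a mean CPM of at least 5. Their difference had a camera adjusted p = 8.292e-10 (adjusted p = 0.134 with an estimated correlation), although the SMYD3_E5Del_Myc call of this list was lost with library-size scaling (adjusted p = 0.184). SPRY4 fell in IT1_del (−0.34) and rose in SMYD3_E5Del_Myc (0.53), a difference of −0.8708 on the log2 scale (edgeR adjusted p = 4.25e-13). SPRY4 hosts SPRIGHTLY, the target of the edit in IT1_del. A local effect of that edit on SPRY4 cannot be told apart from other effects here.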

How the results depend on the processing

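Alternatives chosen only after the results were seen were the olfactory receptor covariate, genes with a mean CPM of at least 5, and leaving out vo replicate 3 with IT1_del replicate 3. Over all alternatives, values of counts and correlations were the same 260 times, moved 85 times and reversed 1 time. Fold changes of named genes were the same 3268 times, weaker 210, stronger 11 and reversed 27. List tests were the same 757 times, weaker 151 and reversed 1, list counts were the same 4931 times and moved 1469, and SMYD3 in the TPM fit was the same 60 times. For every moved or reversed value given here the cause was not tested, except that a minimum fold, a filter or fewer libraries change what is tested. At these depths a count of 0 leaves values under 0.142 to 0.190 CPM (3 counts) open.

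With a minimum of 1.5-fold, higher and lower genes numbered 255 and 258 in IT1_del, 97 and 54 in SMYD3_Myc, 352 and 135 in SMYD3_E5Del_Myc, 1 and 2 between the SMYD3 lines, and 433 and 592 between IT1_del and SMYD3_E5Del_Myc. DESeq2 gave 1232 higher in IT1_del, 2201 lower in SMYD3_Myc, 2296 higher in SMYD3_E5Del_Myc, 466 higher between the SMYD3 lines and 2408 lower between IT1_del and SMYD3_E5Del_Myc. The TPM fit gave 1325 higher in IT1_del, 2080 lower in SMYD3_Myc, 2260 lower in SMYD3_E5Del_Myc, 211 higher and 115 lower between the SMYD3 lines, and 2653 higher between IT1_del and SMYD3_E5Del_Myc. Without a filter there were 1310 lower in IT1_del, 1452 lower in SMYD3_Myc, and 2347 higher and 5307 lower between the SMYD3 lines. Library-size scaling gave 5834 higher and 2765 lower in SMYD3_E5Del_Myc, 462 lower between the SMYD3 lines and 3404 higher between IT1_del and SMYD3_E5Del_Myc. With the covariate, 1224 were higher and 2240 lower in SMYD3_E5Del_Myc, 34 and 62 between the SMYD3 lines, and 3371 and 2073 between IT1_del and SMYD3_E5Del_Myc. Genes with a mean CPM of at least 5 gave 2871 lower in SMYD3_E5Del_Myc, 347 higher and 577 lower between the SMYD3 lines, and 3336 higher between IT1_del and SMYD3_E5Del_Myc. Between the SMYD3 lines, 1933 were higher with only the 2 groups, and 2356 higher and 2652 lower without vo replicate 3 and IT1_del replicate 3.

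Correlations of IT1_del with the difference between the SMYD3 lines were 0.0899 with DESeq2, 0.0737 with TPM and 0.0716 without a filter. For IT1_del and SMYD3_Myc they were 0.46 with DESeq2, 0.478 without a filter, 0.0706 at a mean CPM of at least 5 and 0.424 without vo replicate 3 and IT1_del replicate 3. IT1_del and SMYD3_E5Del_Myc had 0.152 at a mean CPM of at least 5. The SMYD3 lines had 0.868 there, 0.69 with only the 2 groups and 0.755 without the same 2 libraries.

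With each library left out in turn, higher and lower genes ranged from 1286 to 1905 and 1395 to 2577 in IT1_del, 1733 to 2374 and 1869 to 3047 in SMYD3_Myc, 2484 to 4945 and 3094 to 5298 in SMYD3_E5Del_Myc, 246 to 1957 and 358 to 2636 between the SMYD3 lines, and 3080 to 5588 and 2947 to 5096 between IT1_del and SMYD3_E5Del_Myc. Correlations ranged from −0.143 to 0.478 for IT1_del and the difference between the SMYD3 lines, 0.176 to 0.586 for IT1_del and SMYD3_Myc, 0.00262 to 0.672 for IT1_del and SMYD3_E5Del_Myc, and 0.205 to 0.756 for the SMYD3 lines. The negative value came without IT1_del replicate 3.

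The log2FC of PTBP1, SMYD3_Myc vs vo (−0.03, not called), was 0.00631 with RLE factors, 0.0226 with library size, 0.0491 without a filter, 0.0092 with the stricter filter, 0.00641 without abundant genes, 0.00527 with 2 groups, 0.000995 with DESeq2, 0.0279 at a mean CPM of at least 5 and 0.0216 in the TPM fit, and ranged from −0.0416 to 0.0363 without single libraries. Without single libraries the log2FC of PCDH1, IT1_del vs vo (not called), ranged from −0.752 to 1.82. Other genes not called in IT1_del ranged from −0.025 to 0.152 for PTBP1 (called only without IT1_del replicate 3, adjusted p = 0.0362), −0.355 to 0.387 for SPRY4-AS1 and −0.0491 to 0.472 for KCTD16. Without vo replicate 3 and IT1_del replicate 3, SPRY4-AS1 was 0.246 and PCDH1 1.45. With the covariate, PTBP1 in SMYD3_E5Del_Myc was 0.0314, and between the SMYD3 lines SPRY4 was 0.0356, PTBP1 0.0558, SYNE1 −0.0876 and the p of the histone list 0.648.

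Replicate numbers were checked for pairing. Same-numbered libraries of different groups gave 18 pairs, with correlations of their deviations from −0.417 to 0.485, 3 of them over 0.1. These values show no general pairing by number. The highest joined vo replicate 3 and IT1_del replicate 3, the libraries with the most olfactory receptor counts in their lines. The deviations cover all tested genes with their low-count background, so a pairing among more abundant genes is not excluded. With the number as a block, higher and lower genes were 2097 and 2169 in IT1_del, 2064 and 3574 in SMYD3_Myc, 3589 and 4879 in SMYD3_E5Del_Myc, 944 and 1104 between the SMYD3 lines, and 5250 and 3791 between IT1_del and SMYD3_E5Del_Myc.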

Other observations

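Tests chosen only after the result was seen were those of a loss in vo, the low-count background, depth, the covariate, the state of vo, transfection and MYC, together with both added gene lists and the scan along chromosomes. The tests of an extra copy, of a few strong genes and of other splits were set before their results were seen. Members named in the next paragraph were chosen after their values were seen.

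Of 24 neural stem and progenitor genes, 9 fell in SMYD3_E5Del_Myc and SOX9 and PAX6 were among those that rose (camera adjusted p = 0.229), while 6 fell in SMYD3_Myc and SOX9 rose (0.63). In IT1_del 6 of them rose and ID1, ID3 and CD44 fell (0.944). Among 23 SMYD and histone H3 methylation enzymes, 6 rose and SMYD1, SMYD2 and SMYD5 fell in SMYD3_E5Del_Myc (0.958), 6 rose and SMYD1, SMYD2, SMYD5 and NSD1 fell in SMYD3_Myc (0.414), and SMYD1, SETD1B, KMT2B, KMT2D and NSD2 rose and KDM5A, SETD2 and NSD1 fell in IT1_del (0.944). Of 26 apoptosis regulators, 7 rose and 7 fell in SMYD3_E5Del_Myc (0.958), BMF and APAF1 rose and 6 fell in SMYD3_Myc (0.795), and BAX and TNFRSF10B rose and BMF was among those that fell in IT1_del (0.944).

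Photoreceptor genes of Group 3 medulloblastoma had 13 measured members. CRX, GABRA5, TRPM3 and AIPL1 rose and MYC and ARR3 fell in IT1_del (camera adjusted p = 0.214). NRL and CRX rose in SMYD3_Myc, where GABRA5, IMPG2, MYC, GNGT1 and AIPL1 fell (0.29). CRX, TRPM3 and GNAT1 rose in SMYD3_E5Del_Myc, where GABRA5, MYC, PDE6H, AIPL1 and ARR3 fell (0.472). The 9 WNT-type markers moved both ways in each line and did not pass camera (0.822 in IT1_del, 0.972 in SMYD3_Myc and 0.958 in SMYD3_E5Del_Myc). Among 7 HOX genes, HOXC8 rose in IT1_del, HOXC4 fell in SMYD3_Myc and HOXB3 rose in SMYD3_E5Del_Myc (0.842, 0.323 and 0.958). OCLN, of 7 epithelial markers, fell in IT1_del and SMYD3_E5Del_Myc (0.743 and 0.975). The 6 immune markers did not pass camera in any line (0.842, 0.551 and 0.975). Of 10 endothelial markers, with a median of 0.78, VWF, FLT1, ESAM and ERG rose and EGFL7 fell in SMYD3_E5Del_Myc (0.173), the line with the most olfactory receptor counts, and 11 of 21 interferon genes rose there with HLA-B among those falling (0.472).

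MYC fell in both SMYD3 lines (−0.88 and −0.86) and differed little between them (0.01, edgeR adjusted p = 0.904). It also fell in IT1_del, by less (−0.21, adjusted p = 0.000839). Of 39 MYC growth targets, among them TFB2M and SRSF1 of other lists, 34 fell in SMYD3_Myc (median −0.37, camera p = 6.67e-19, p = 0.0306 with an estimated correlation). In SMYD3_E5Del_Myc 36 fell and SRSF1 rose (median −0.40, camera p = 2.079e-16, p = 0.0415 with an estimated correlation). The median between the SMYD3 lines was −0.01 (camera p = 0.393), and in IT1_del 4 rose and 6 fell (p = 0.0411, p = 0.564 with an estimated correlation). Lower MYC is a candidate explanation for the fall of these genes, on data in which both had been seen. Of 31 skeletal muscle genes, 5 rose and 13 fell in SMYD3_Myc (camera p = 0.0111, p = 0.02 with an estimated correlation), 10 and 13 in SMYD3_E5Del_Myc (0.309) and 10 and 10 in IT1_del (0.502). MYOG, MYOD1, TTN, CKM, TNNT1, MRLN, CASQ2, KLHL41 and CDH15 fell in each of these lines, and TNNI1 and PAX3 rose in each. The fall of those muscle genes against vo is thus not particular to the SMYD3 lines.

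On chromosome 2, 194 genes of a 170.81 to 227.72 Mb stretch had a median log2 fold change of 0.29 in IT1_del against vo, and library medians of 0.248, 0.301 and 0.291 (permutation of genes, p = 0.00498, the smallest it can give). That p is not particular to this stretch. The scan gave it to 6 stretches in SMYD3_E5Del_Myc against vo and 3 between the SMYD3 lines, with medians from −0.19 to 0.13, and to 1 on chromosome 3 in IT1_del. The scan statistic was 17.1 here and at most 8.48 in those. A few strong genes are argued against, since the median was 0.2765 without 20 genes called with over 1.5-fold change. A loss in vo alone is argued against as well, since the larger median in the SMYD3 lines was 0.02096. A loss that vo and both SMYD3 lines share would give such a median too, so this test cannot address it. An extra copy in the IT1_del line may account for it: 39 genes of 1 to 5 CPM, outside the scan, had a median of 0.376 against a 95th percentile of 0.129 for random sets. A change of regulation over the stretch would move those genes too and stays open. Copy number was not measured, so the median of 0.29 was not set against an expected size. In the same comparison, 20 genes on chromosome 3 (45823316 to 48444208) had a median of −0.48, or −0.05 without 10 genes called with over 1.5-fold change. A neighbouring stretch of chromosome 2 (150.47 to 167.87 Mb, 25 genes) had a median of 0.20, with 12 genes called higher (permutation p = 0.0398), so where an extra copy would begin is open.

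Genes of low count were higher in SMYD3_E5Del_Myc, where 1350 such genes summed to between 1289 and 1765 CPM against 227 to 597 in vo. Deeper sequencing is argued against by a ratio of mean totals of 0.8945. A background that differs between libraries of 1 line may contribute, since the sum was at least 1.715 times higher in the library of most than of least olfactory receptor counts within vo, IT1_del and SMYD3_Myc. With those counts as a covariate 32 of 1361 calls were left, but each SMYD3_E5Del_Myc library lies above each other library in background. Transcription in that line and the background cannot be told apart.

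Among genes with a mean CPM of at least 5, 4033 were called in both SMYD3 lines and moved the same way. Relative to the median of genes at that level, 1107 were higher and 2926 lower in both. The calls came from the main fit and were not recentred. Its medians at that level were −0.06 in SMYD3_Myc and −0.11 in SMYD3_E5Del_Myc, so the excess of lower genes may come from scaling. A fit of only such genes gave 2671 higher and 2650 lower in SMYD3_Myc, and 2830 and 2871 in SMYD3_E5Del_Myc. The median change of the 4033 genes in their direction was 0.268 in SMYD3_Myc, 0.281 in SMYD3_E5Del_Myc and 0.0332 in IT1_del. The state of the vo libraries as the whole cause is argued against by a ratio of 0.1241 between IT1_del and the smaller of the others. Transfection and selection cannot be told apart from the added SMYD3, since the correlation of 0.8681 between the lines holds for either and no line with transfection alone is named. Clonal differences stay open too.

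Splits of the 6 libraries of a comparison number 10, too few for a share under 0.05. In each comparison 1 split, the real one, reached its own number of calls. It gave 4134 in IT1_del, 5486 in SMYD3_Myc, 8559 in SMYD3_E5Del_Myc, 2140 between the SMYD3 lines and 9079 between IT1_del and SMYD3_E5Del_Myc. The highest other split called 0 genes with edgeR in each, with 2605, 1569, 1959, 1368 and 1605 genes at an unadjusted p under 0.05. Each other split mixed libraries of both lines within its groups, which adds the difference between the lines to the spread. Few calls were therefore likely in advance, and the 0 calls do not measure what unchanged lines would give.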
